A study of Mus musculus with 18 samples.

How the data were processed

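RNA from MEL cells on days 0, 1, 2, 3, 4, 5 and 6 after HMBA was set against RNA of uninduced cells on 18 two-colour arrays, per the labels. The channel that held induced RNA was named in the labels, but the dyes, the scanner, the image analysis and the normalization were not given in the sources used here. Titles gave the day, a series letter A or B and, for 5 arrays of series B, the word SD. The deposited table held log2 ratios, a scale recognised from its values, because low values on the 13 other arrays were the log2 of a ratio with 3 decimals. On the SD arrays the high values were minus the log2 of such a ratio, so their sign appeared to have been turned before deposit. The numerator channel, any earlier normalization and the reason for the turned sign stayed unknown, and so did the direction as such.

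Values were not centred as deposited. The array medians in series A were -0.09, 0.03, 0.07, 0.06, 0.26, 0.29 and 0.55 log2 from day 0 to day 6. In series B they were 0.30, 0.37, 0.36, 0.63, 0.27 and -0.0022 on days 0, 2, 3, 4, 5 and 6. The SD arrays had medians of 0.52, 0.15, -0.15, 0.48 and 0.70 on days 0, 2, 3, 5 and 6. Each array was centred on its median. The deposited table gave no spot intensities that were used here, so the signal behind a ratio was not known. Between 29.2 and 72.0 percent of the 6868 probes had a value on the 13 arrays other than SD.

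Probes were named from the platform annotation, in which 6108 had 1 gene symbol, 41 had several and 719 had none. Symbols were checked against a gene table through Entrez identifiers, where 6062 matched and 0 needed an update. A probe was tested when at least 11 of the 13 arrays and at least 1 day 0 array held a value, which left 1221 probes.

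The groups were the 7 days, fitted as means without further terms by limma 3.58.1 in R 4.3.3, with moderated tests and Benjamini-Hochberg adjustment at 0.05. Every contrast drew on a spread shared by all groups (prior degrees of freedom 10.4, prior SD 0.97 log2). Contrasts were each day against day 0, early (days 1 and 2), late (days 4, 5 and 6), late minus early, any day by an F test, and a linear trend. The median standard error was 0.82 log2 for the late contrast and 1.04 for day 2. The tests, the gene lists, the rule for naming genes and most alternatives were set before the data were examined.

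The rule for SD arrays set in that plan was not followed. It read a positive correlation of SD arrays with the B arrays of the same days as a sign that the authors had already turned them, and then averaged both. The median correlation across probes was 0.475 (0.419 to 0.581 over days 2, 3, 5 and 6). Since the day 0 arrays, which hold no induced RNA, also correlated with them, that rule could not tell a shared probe bias from induction. After probes with large changes were seen to run the opposite way on SD arrays, the 5 SD arrays were left out. Applied as planned, averaging also called 0 probes in every contrast, with 15 late probes at an unadjusted p under 0.05 and Hba-ps3 late at 2.76 log2. It was kept as an alternative.

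The direction was called likely induced over control because the globin and heme synthesis lists both had a positive late median, 1.30 over 2 probes and 1.12 over 5. The heme median was below 0 without day 0 of series B, day 4 of series A or day 5 of series A, and the globin median was above 0 without each day 0 or late array. That basis is textbook knowledge that HMBA induces hemoglobin synthesis, and the labels named channel 1 as the induced one on these arrays.

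Genes were named by rule. For the late contrast the rule took up to 10 higher and 10 lower probes with 1 symbol, past the threshold and with the same sign on every late array. For early and for late minus early it took 5 each way, for single days 3 each way, and the list members with the smallest late p-values. Where too few passed, the smallest p-values filled the number and are given as not past the threshold. Globins, Gata1, Myb and Myc were always included where measured. The slopes of the trend and the further members of lists given in the text were chosen after their values were seen. The 34 preset lists were tested with camera at a preset correlation of 0.01, with an estimated correlation as an alternative and fry beside it, when at least 5 genes were measured. Values of list members below the filter came from a fit without it. Some tests were judged to decide nothing under conditions added after their values were known. These were the tests on the channel order of SD arrays, on the day 0 profile of series A and on the late calls with that profile removed, and the count of splits.

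The steps were tested on simulated data shaped like the 13 arrays, with 200 of 1221 probes changed late in 10 simulations. The fit recovered 1.40, 14.8, 55.6 and 86.1 percent of changes of 1, 2, 3 and 4 log2, with 1.9 false calls on average and 0 when nothing changed. With the day 0 profile removed it recovered 38.3, 89.3, 99.4 and 100 percent, but 39.2 of 200.8 calls were false. The ratio tested against 0 gave 129.2 false calls when nothing changed, since a probe bias then counts as change. Simulated ratios were the day 0 profile at each array's real slope plus independent noise of equal size on all arrays. They held no further difference between the series, so these rates may not carry over to the real arrays.

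The alternatives tried were the series letter as a block, SD arrays averaged as deposited, an array-level fit of all 18 arrays with an orientation term, the ratio tested against 0, values as deposited, equal spread, quantile normalization, other filters on missing values, a robust prior, probes averaged per gene, a minimum change of 1 log2, and leaving out each array. Alternatives chosen after seeing the data were SD arrays turned and averaged, the day 0 profile removed with and without them, leaving out series A of days 1, 2 and 3, and 2 further scalings for the lists. With the profile removed, what was left of each ratio was tested against 0. The profile was then taken as known, so these standard errors and p-values leave out the error of the day 0 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.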

Results

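Gene expression was followed over 6 days in murine erythroleukemia (MEL) cells, an established mouse line of transformed erythroid precursors that differentiates toward hemoglobin-making cells under hexamethylene bisacetamide (HMBA). Each of 18 two-colour arrays set RNA from a day after HMBA against RNA of uninduced control cells. Arrays of day 0 held control RNA in both channels. Series A covered days 0, 1, 2, 3, 4, 5 and 6 with 1 array each. Series B covered days 0, 2, 3, 4, 5 and 6. A further 5 arrays of series B were titled SD. On those of days 2, 3, 5 and 6 the channel labels of induced and control RNA were exchanged, and that of day 0 held control RNA in both channels. The comparisons rested on the 13 arrays of series A and B other than SD, so that every day had n = 2 apart from day 1 with n = 1, which was assumed to vary like the other groups. Between 2008 and 4945 of 6868 probes had a value on these arrays, and 1221 probes with a value on at least 11 of the 13 entered the tests. Values are log2 ratios centred on each array's median, with the likely direction induced over control. Nothing in the labels said that the arrays came from separate cultures, so p-values measured only the spread between arrays, which may be technical. The number of arrays limited the precision.

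The late comparison, the mean of days 4, 5 and 6 against day 0, asked which transcripts differed once cells had been in HMBA for most of the course. A probe of the alpha-globin family (symbol Hba-ps3, probe M004980_01) had the largest late difference among the named genes. Hbb-b2, an adult beta-globin, was higher on all 6 late arrays as well. Alas2, which encodes the erythroid enzyme of the first step of heme synthesis, was 3.60 log2 higher than on day 0 on the 4 of 4 late arrays that measured it. Tfrc, the receptor that brings transferrin-bound iron into erythroid cells, was 2.76 log2 higher on 4 of 4 arrays. Ftl1, the light chain of the iron store ferritin, was 2.09 log2 higher on 6 of 6 (mean ratios of 0.54 late and -1.54 on day 0). The list of iron handling that holds both had a median of 0.34 as a whole (4 of 5 tested genes higher, adjusted p = 0.842 in limma's camera). Of its 7 measured probes Slc11a2 and Slc40a1 were lower on every late array. Myb, a transcription factor that keeps erythroid progenitors dividing, was lower on 6 of 6 arrays.

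The Hba-ps3 probe was 4.43 log2 higher late (SE 0.89), a 21.6-fold difference seen on 6 of 6 arrays. With an adjusted p = 0.183 in limma it was not past the threshold of 0.05, but it was past it with the series letter as a block. Its mean log2 ratio was 0.59 on day 0, 0.69 on day 1, 2.22 on day 2, 3.90 on day 3, 5.67 on day 4, 5.39 on day 5 and 4.00 on day 6. The symbol names a pseudogene of the alpha-globin family, and transcripts of near-identical alpha-globin genes could not be separated from it on such an array. Hbb-b2 was 2.34 log2 higher late (SE 0.85, 6 of 6 arrays). Embryonic Hba-x was 0.26 log2 higher late on 4 of 6 arrays, and below day 0 with quantile normalization, without day 0 of series B (-0.29) or without day 6 of series B (-0.20). A further Hba-x probe was measured on days 0, 1 and 2 alone (-0.28 and -1.80 on 1 array each, and a mean of -0.64 over 2). Hbb-bh1, an embryonic beta-like globin, had means of -0.46 on day 0, -0.63 on day 1, -1.36 on day 2, -0.21 on day 4 and -0.74 on day 5, with 1 array each on days 1 and 5, and Hbb-bh0 had single values of -1.76 on day 1 and -0.57 on day 5. Among enzymes of heme synthesis, Alad was 1.49 and Fech 1.12 log2 higher, on 4 of 6 and 4 of 5 arrays, while Ppox was 1.52 log2 below day 0 on 4 of 4 arrays (-1.52) and Cpox differed by -0.41. Alad was at 0.18 without day 0 of series B, 2.81 without day 0 of series A and 0.96 and 0.89 without days 4 and 5 of series A. Fech was at 0.44 without day 5 of series A and 1.81 without day 5 of series B. Alas2, Tfrc, Fech and Ppox each rested on 1 day 0 array. For Alas2 that was the array of series B (-0.69), while its late values came from days 4, 5 and 6 of series A and day 6 of series B. The SD array of day 0, left out of the fit, read 1.28 for Alas2. The median over the 5 heme probes was 1.12, but it was -0.29 over 6 probes when ratios were not set against day 0, and -0.60 when SD arrays were turned and averaged in. It was also below 0 without day 0 of series B (-0.11 over 4 probes), day 4 of series A (-0.62 over 3) or day 5 of series A (-0.10 over 4). Because the globin and heme lists served to choose the likely direction, they are no independent evidence of it. Values of Alas2, Tfrc, Fech, Alad and Ppox came from 9 or 10 of the 13 arrays, under the minimum for testing.

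**Figure D1:**
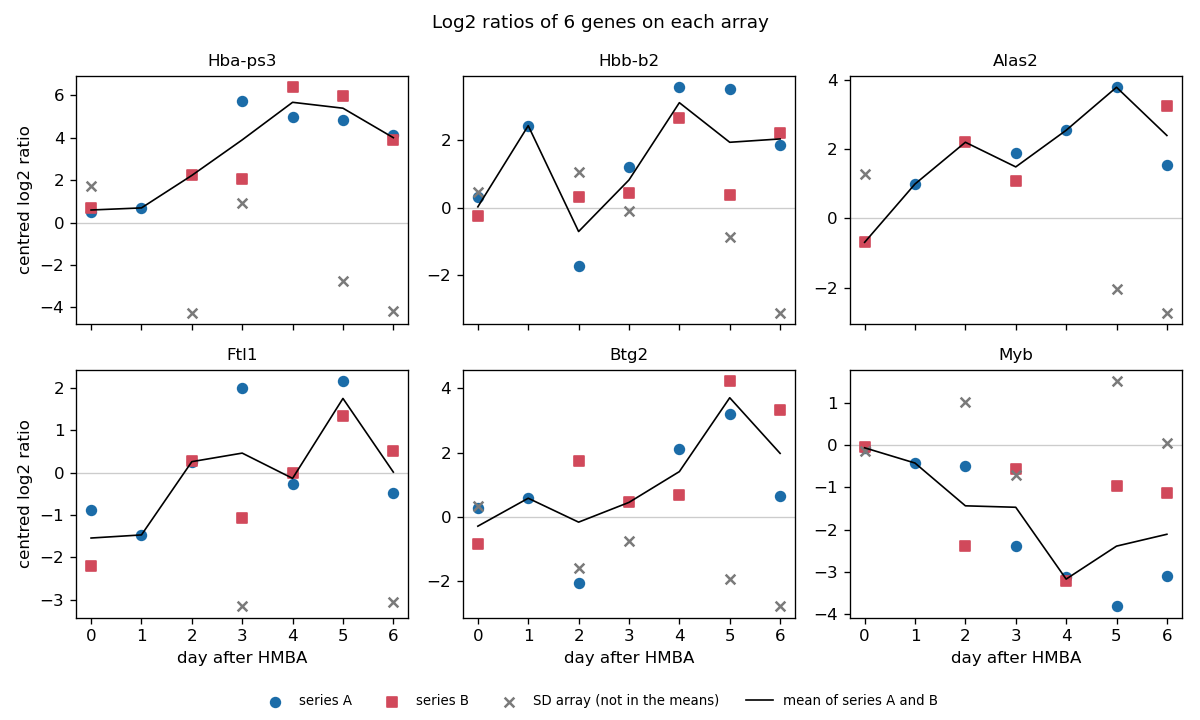
Centred log2 ratio (vertical axis) by day after HMBA (horizontal axis) for 6 genes, with 1 point per array of series A, series B and SD, and a line through the mean of series A and B. The likely direction is induced over control for series A and B, and it stays open for SD arrays. Hba-ps3 climbs from 0.59 on day 0 to 5.67 on day 4, Myb reaches -3.17 on day 4, and SD points lie mostly on the other side of 0 from series A and B on induced days.

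Further genes with the smallest late p-values included regulators of growth and of the cell surface. Btg2, which encodes an antiproliferative protein, was 2.65 log2 higher late (SE 1.00, 6 of 6 arrays), and its mean ratio was 3.71 on day 5. Mknk2, a kinase of the translation factor eIF4E, was 2.86 log2 higher (SE 0.94, 6 of 6, against 1 day 0 array). Itga2b, an integrin chain of megakaryocytes and early progenitors, was 2.49 log2 higher (SE 0.77, 6 of 6). Mt2, a metal-binding metallothionein, was 2.38 log2 higher and Actg1, a cytoplasmic actin, 1.95 log2 higher, each on 6 of 6 arrays. Mean ratios of Mt2 and Actg1 were 0.62 and 0.85 late and -1.76 and -1.10 on day 0. The sphingosine phosphate receptor S1pr2 was 2.14 log2 higher on 5 of 5 arrays, and Rnf11, a ubiquitin ligase component, was 1.85 log2 higher on 6 of 6. Without day 0 of series B, Actg1 was at 1.26 and Rnf11 at 1.03. All of these had an adjusted p = 0.9999 in limma.

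On the lower side, Myb was -2.49 log2 from day 0 (SE 0.88, 6 of 6 arrays), with means of -0.07 on day 0 and -3.17 on day 4. The heparan sulfate enzyme Ndst2 had the lowest value, -3.19 (SE 0.99, 5 of 5 arrays). Integrin alpha 4, encoded by Itga4 and used by progenitors to hold to stroma, was at -2.12 on 5 of 5 arrays, and Slc11a2, an importer of iron, was at -1.67 on 6 of 6. Cdc7, a kinase that fires replication origins, was at -1.53, and Timeless, a protein of the replication fork, at -1.58, each on 5 of 5 arrays. Rrs1, needed for ribosome assembly, was at -1.52, the helicase gene Ddx3x at -1.85, the Rac activator gene Tiam1 at -1.85 and Coil, the scaffold of Cajal bodies, at -1.64. None was past the threshold, with adjusted p = 0.9999 in limma for each of these 10. Directions of Tiam1, Ddx3x and Rrs1 reversed when ratios were tested against 0 and not against day 0. With the day 0 profile removed Slc11a2 was at -0.79, Rrs1 at -0.60, Tiam1 at -1.04 and Ddx3x at -1.10.

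Over all 1211 probes that the late comparison could fit, limma called 0 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 28, 21 higher and 7 lower, against 60.55 expected by chance, and there were 3 without day 0 of series B and 18 without day 4 of series A. The fit over all 18 arrays with an orientation term called 1, the Hba-ps3 probe. Leaving out day 3 of series A or of series B kept its late difference at 4.43 log2, because day 3 is not part of that contrast. Only its spread changed, since its day 3 values of 5.73 (series A) and 2.07 (series B) lay far apart. The planned fit with the series letter as a block called 1 as well, again Hba-ps3. The main fit had no term for the letter, so any difference between the series counted as spread. Testing the late ratios against 0 gave 268 calls, and removing a scaled day 0 profile from each array gave 56. The p-values of both fits leave out the error of the day 0 arrays. The median late difference over the tested probes was 0.21 log2, and it became 0.46 without centring.

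**Figure D2:**
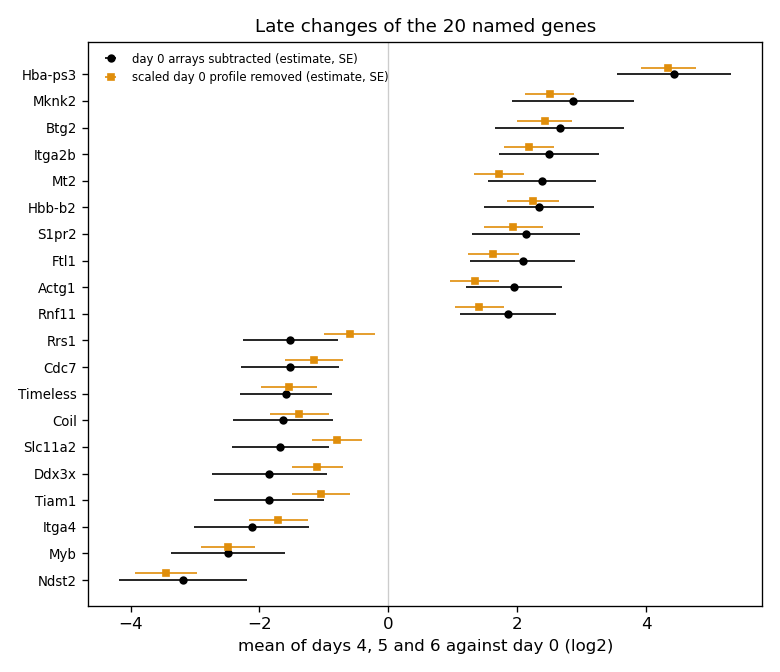
Late difference from day 0 in log2 (horizontal axis) with its standard error for the 20 named genes (vertical axis), with day 0 arrays subtracted (circles) or with the scaled day 0 profile removed (squares). Both estimates rest on the same late arrays and keep their sign for each of the 20 genes. The standard error of Hba-ps3 is 0.89 with subtraction and 0.43 with removal. Removal takes the profile as known and leaves out the error of the day 0 arrays, so the smaller value is no gain in precision.

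Of genes of DNA replication, Mcm4, Mcm5 and Mcm7, parts of the helicase that opens origins, were at -1.17, -0.85 and -1.17 log2, each on 6 of 6 arrays. Pcna, the sliding clamp of the polymerases, was at -0.88 on 6 of 6 arrays, and Mcm3 at -1.65 on 4 of 4. Uhrf1, which carries DNA methylation through replication, was at -1.65 on 5 of 5 arrays. Over every measured probe of the replication list, 22 of 30 were lower and 8 higher, with a median of -0.51, and the median stayed negative without centring (-0.20), with equal spread (-0.31) and with quantile normalization (-0.41). It was 0.06 without day 0 of series A, where 11 of 19 probes were higher. Mcm5 was then at 0.05, and at -1.76 without day 0 of series B, and Mcm4 at -0.77 without day 5 of series A. Of all 2615 probes with a late value, 1061 were lower. Among the 15 genes of the list that passed the filter the median was -0.23, and camera in limma gave an adjusted p = 0.234 (9 of 15 genes lower). It was -0.71 (adjusted p = 0.0462) without day 6 of series A and -0.52 (adjusted p = 0.00984) without day 0 of series B.

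Of mitotic genes, Smc2, a condensin subunit, was at -0.80 on 5 of 5 arrays, the tubulin gene Tubb5 at -1.03 and Racgap1, which acts in cytokinesis, at -0.86. Over the 6 tested genes of the mitosis list the median was -0.66, with 5 lower, and camera in limma gave an adjusted p = 0.0964, but an adjusted p = 0.00961 with an estimated correlation, which was -0.0971. A negative estimate makes that test more lenient than the preset 0.01. Over all 17 measured probes of that list the median was -0.64, with 12 lower, but -0.26 without day 0 of series A and -1.04 without day 0 of series B. Without these arrays in turn, Smc2 was at -1.28 and -0.31 and Racgap1 at -0.30 and -1.42. The list for nucleolus and ribosome assembly had a median of -0.53 with 5 of 6 genes lower, among them the helicase gene Ddx21 at -1.43 on 6 of 6 arrays, and the same adjusted p = 0.0964, or 0.113 with an estimated correlation. Over its 10 measured probes the median was -0.33, but 0.04 with equal spread of the arrays. The list of progenitor factors had a median of -0.56 with 4 of 6 genes lower and again an adjusted p = 0.0964. Over all 10 measured probes of that list 5 were higher and 5 lower, with a median of 0.14, or -0.43 when SD arrays were turned and averaged in. Leaving out single day 0 or late arrays put it between -0.95 (day 6 of series A) and 0.47 (day 0 of series A), with -0.34 without day 0 of series B. The median of the 6 tested genes was above 0 when ratios were tested against 0. The lists of mitosis and of progenitor factors passed without day 6 of series A (-0.73 and -0.95) and without day 0 of series B (-0.70 and -0.71). Camera with the preset correlation called 0 of 21 lists late, and 3 had an unadjusted p under 0.05. Gata1, the central transcription factor of the erythroid lineage, was at 0.67 on 4 of 5 arrays, but at -0.64 without day 0 of series B and 1.97 without day 0 of series A. Myc was at -0.03, or 0.47 and -0.53 without day 0 of series A or B. The list of erythroid transcription factors had a median of 0.46 (4 of 6 genes higher, adjusted p = 0.878 in limma), which was below 0 when ratios were tested against 0 and -0.10 with the day 0 profile removed.

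The early comparison, days 1 and 2 against day 0, asked which transcripts differed soon after induction. Prdx2, a peroxidase that is abundant in red cells, was 3.03 log2 higher (SE 1.05, 3 of 3 arrays). Pabpc1, which binds poly(A) tails, was 3.08 log2 higher, and the ribosomal protein gene Rps18 was 2.56 log2 higher, each on 3 of 3 arrays. The transcription coactivator gene Edf1 was 3.02 and Cox7c, a subunit of cytochrome c oxidase, 3.00 log2 higher, each on 3 of 3 arrays. Mean ratios of Prdx2, Pabpc1, Rps18, Edf1 and Cox7c over the early arrays were 0.11, 0.0052, -0.21, 0.40 and -0.40. On day 0 they were -2.83, -2.86, -2.69, -2.60 and -3.30, so these differences came mostly from the day 0 arrays. Lower values were seen for the Myc antagonist Mnt (-2.11, 2 of 3 arrays), the transcription factor Yy1 (-2.32, 2 of 2), Rrs1 (-1.98, 3 of 3), Gsdma (-2.06, 3 of 3) and Gpr37 (-1.90, 3 of 3). Limma called 0 of 1060 probes, with 37 at an unadjusted p under 0.05 (53 expected by chance) and an adjusted p = 0.999 for each named gene. That 37 became 0 without day 0 of series B, 12 without day 2 of series A and 73 without day 2 of series B. Without day 0 of series B, Prdx2 was at 1.43, Pabpc1 at 1.74 and Cox7c at 1.59, and without day 0 of series A Prdx2 was at 4.64. The fits with the ratio against 0 and with the profile removed each called 0 as well, and each of the 10 sizes was smaller with the profile removed. Prdx2 was then at 1.05, Rps18 at 0.69, Cox7c at 0.75, Rrs1 at -0.38 and Gpr37 at -0.20. Directions of Rps18, Cox7c, Rrs1 and Gpr37 reversed when ratios were tested against 0.

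Ribosomal proteins as a preset list rose early by camera, with a median of 2.03 log2 and 15 of 15 genes higher (limma's camera, adjusted p = 4.41e-07). It had an adjusted p = 0.753 with an estimated correlation. With the day 0 profile removed the median was 0.34 and the call was lost (adjusted p = 0.861). Rpl19 was 2.81, Rpl21 2.59 and Rpl8 2.40 log2 higher. Mitochondrial respiration rose by the same test, with a median of 1.17 and 10 of 12 genes higher (adjusted p = 0.0130), and had an adjusted p = 0.753 with an estimated correlation. With the profile removed its median was 0.35 (adjusted p = 0.979). Ndufa2, a subunit of complex I, was 2.15 and Atp5b, a subunit of ATP synthase, 1.88 log2 higher. The call of mitochondrial respiration was lost without day 2 of series A (0.94, adjusted p = 0.0937) or day 0 of series B (0.64, adjusted p = 0.129). Both medians kept their sign without centring, with equal spread and with quantile normalization, and reversed when ratios were tested against 0. In each list, 0 genes passed the threshold over all genes, and 0 when adjusted over the list alone. The rotation test fry, which needs genes with all 13 values, gave the 9 ribosomal genes it could use an adjusted p = 0.340.

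Between the early and the late days, the alpha-globin probe Hba-ps3 was 3.57 log2 higher late than early (SE 0.89). Mknk2 was 1.83 log2 higher, and the transcription factor gene Ebf3 2.89, the collagen gene Col9a2 2.31 and the glycine receptor gene Glra1 2.15 log2 higher. Ndst2 was at -2.96, the chaperonin gene Cct4 at -2.99, the ribosomal protein gene Rps12 at -2.76, D17H6S56E-5 at -2.09 and the selenoprotein gene Selenow at -1.90. These 10 genes each had an adjusted p = 0.730 in limma, which called 0 of 1050 probes, while 67 had an unadjusted p under 0.05 (52.5 expected by chance). There were 20 without day 2 of series A, where Ndst2 was at -1.91, 137 without day 2 of series B, and 40 and 39 without days 5 and 6 of series B. Relative to day 0, Hba-ps3 and Cct4 held their late direction on 6 of 6 arrays (Cct4 against 1 day 0 array) and Rps12 on 2 of 6. All other fits called 0.

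The ribosomal protein list fell between early and late, with a median of -1.65 and 15 of 15 genes lower (limma's camera, adjusted p = 4.95e-09), and had an adjusted p = 0.367 with an estimated correlation. With the day 0 profile removed the median was -0.89 (adjusted p = 7.66e-06, and adjusted p = 0.0471 with an estimated correlation). Early arrays of series A carried little of that profile, with slopes on it of 0.15 on day 1 and -0.01 on day 2. Day 2 of series B had 0.99, and the late arrays 0.41 to 1.13. How far this accounts for the fall stays open. Mitochondrial respiration fell by a median of 0.76 log2 with 11 of 12 genes lower (adjusted p = 0.0438), and had an adjusted p = 0.509 with an estimated correlation. With the profile removed its median was -0.20 and the call was lost (adjusted p = 0.762). It was also lost without day 2 or day 6 of series A (adjusted p = 0.232 and 0.0734) and without day 4 or day 5 of series B (0.0565 and 0.0973), with equal spread of the arrays (0.0901) and with quantile normalization (0.0859). Late values of ribosomal protein genes against day 0 were divided, with 8 of 16 higher and a median of -0.03, but it was -0.63 (adjusted p = 0.00984) without day 0 of series B. In both lists 0 genes passed over all genes, and 0 when adjusted over the list alone.

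On day 1 the phosphatase gene Ptp4a2, the cap-binding gene Eif4e2 and the asparagine synthetase gene Asns were 4.03, 3.51 and 3.42 log2 higher on the single array. Ptp4a2 had a value on only 1 day 0 array. Ncam1, Mnt and Yy1 were at -3.47, -3.33 and -3.31. Day 2 had Lamp1, a lysosomal membrane protein, 3.54 log2 higher on 2 of 2 arrays and the proteasome gene Psma7 2.55 log2 higher on 2 of 2. The alkaline phosphatase gene Alpl was 2.83 log2 higher on 1 of 1 array, while Vmn2r129, Anxa5 and Deaf1 were at -2.55, -2.07 and -2.33. Limma called 0 probes on day 1 and 0 on day 2, with 37 and 25 at an unadjusted p under 0.05 (53.05 and 61 expected by chance). These became 3 and 2 without day 0 of series B, and the 25 became 10 without day 2 of series A and 87 without day 2 of series B. Leaving out these day 2 arrays in turn put Vmn2r129 at -1.27 and -3.83 and Deaf1 at -1.06 and -3.59, and Lamp1 was at 1.95 without that of series A. Adding a term for the orientation of the channels over all 18 arrays called 1 probe without a gene name on day 2.

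Day 3 was the first day on which the Hba-ps3 probe had one of the smallest p-values, 3.31 log2 higher on 2 of 2 arrays, but 1.48 without day 3 of series A and 5.14 without day 3 of series B. Cox7c and Ptp4a2 were 4.58 and 3.75 log2 higher on 1 of 1 array, Ptp4a2 against 1 day 0 array. Plin2, a coat protein of lipid droplets, was at -4.59 on 1 of 1 array, the junction protein gene F11r at -3.03 on 2 of 2 and Snap91 at -3.43 on 1 of 1. Limma called 0 of 1212 probes, with 31 at an unadjusted p under 0.05 (60.6 expected by chance), and the ratio tested against 0 called 1. That 31 moved both ways when single arrays were left out.

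On day 4 Hba-ps3 was 5.08 log2 higher (SE 1.09, 2 of 2 arrays, adjusted p = 0.347 in limma). S1pr2 was 3.35 log2 higher on 2 of 2 arrays and Col9a2 4.08 on 1 of 1, while Ndst2 was at -3.70, Myb at -3.10 and Rrs1 at -2.84, each on 2 of 2. Day 5 had Hba-ps3 4.80, Btg2 4.00 and Ftl1 3.30 log2 higher, and Cdc7, Tubb5 and the arginine synthesis gene Ass1 at -3.00, -2.90 and -2.68, each on 2 of 2 arrays. Day 6 had Hba-ps3 3.41 and the adenylate kinase gene Ak4 2.55 log2 higher on 2 of 2 arrays, the lysosomal protease gene Ctsl 4.37 higher on 1 of 1, and Zfx, Itga4 and Tiam1 at -2.35, -2.65 and -2.39. Limma called 0 probes on each of days 4, 5 and 6, with 39, 56 and 25 at an unadjusted p under 0.05 (61, 60.75 and 60.9 expected by chance). These became 9, 8 and 3 without day 0 of series B, and the 25 became 13 without day 6 of series B. S1pr2 on day 4 was at 1.99 without that array of series B, and without those of series A Ass1 on day 5 was at -1.59 and Itga4 and Tiam1 on day 6 at -1.69 and -1.24. Ratios tested against 0 gave 15, 3 and 1 calls on these days. With the series letter as a block, Hba-ps3 passed on days 4 and 5 and Ctsl on day 6. Without day 3 of series A, or without day 3 of series B, Hba-ps3 on day 4 stayed at 5.08 log2 and only its spread changed.

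A linear trend over the 7 days asked for steady change and did not rest on day 0 alone. Hba-ps3 had a slope of 0.78 log2 per day (SE 0.17), the smallest p-value of the trend (adjusted p = 0.150 in limma, 12 arrays). Ndst2 had a slope of -0.67 (SE 0.18) with an adjusted p = 0.535. Btg2, Itga2b and Myb had slopes of 0.54, 0.42 and -0.41 per day. The trend called 0 of 1221 probes, with 41 at an unadjusted p under 0.05 (61.05 expected by chance). An F test of any difference on days 1 to 6 called 0 of 1041, with 22 (52.05 expected by chance). That 22 moved both ways when single arrays were left out. For the trend, the fit over all 18 arrays with an orientation term called 3, Hba-ps3, Btg2 and Itga2b.

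Arrays also differed in how strongly they carried the probe pattern seen when control RNA was set against itself. The day 0 arrays of series A and B, which hold no induced RNA, correlated with the SD array of day 0 at 0.655 and 0.656, and with each other at 0.735. Such correlations run across genes, which are not independent replicates. The slope of each array on this day 0 profile was 0.72 for day 0 of series A and 0.15, -0.01 and 0.18 on days 1, 2 and 3 of that series. It was 0.61, 0.41 and 0.48 on its days 4, 5 and 6, and between 0.69 and 1.15 on series B.

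**Figure D3:**
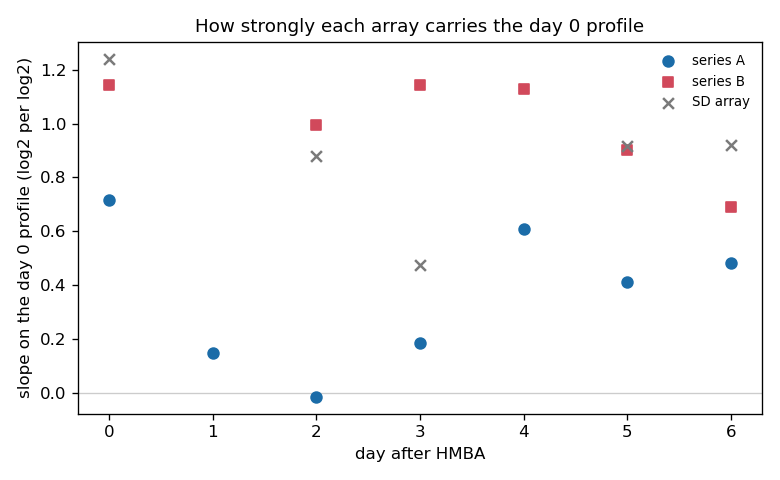
Slope of each array's log2 ratios on the mean day 0 profile (vertical axis, log2 per log2) by day after HMBA (horizontal axis), with 1 point per array of series A, series B and SD. Series A lies at 0.15, -0.01 and 0.18 on days 1, 2 and 3, and series B between 0.69 and 1.15.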

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

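All tests in this part were chosen only after the results were seen.

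The SD arrays drew attention as data outside the comparisons that carried a clear signal. Over the probes that differed by at least 2 log2 late in series A, each SD array was set against the series A late difference. The correlation across these probes was -0.487 on day 2, -0.190 on day 3, -0.659 on day 5 and -0.680 on day 6. On the B arrays of the same series it lay between 0.574 on day 2 and 0.891 on day 4. These were 9 relations across 13 to 24 probes, which are not independent replicates. Permutation gave p = 0.0126, 0.440, 0.000350 and 0.000510 for the 4 SD arrays, and 0.0142, 0.440, 0.00119 and 0.00119 after adjustment over the 9. The SD array of day 0 minus the B array of day 0 gave 0.248.

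If SD values had already been turned to the direction of the other arrays, these correlations should have been positive. Their median of -0.573 argues against that. Values that keep the channels in the order of the other arrays would put induction on the opposite sign, and the highest of the 4, -0.190, was below 0. That explanation was found from these same values, so they lend it no support, and in which order the SD arrays hold the channels stays open. No biological explanation was tested, because the labels give these arrays the same days and cells, and a mislabelled channel stays open.

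A further pattern was in series A, where days 1, 2 and 3 against day 0 mirrored the day 0 profile. The change on each of these arrays was set against the day 0 array of series B, which shares no array with it, and the correlation across probes was -0.446, -0.477 and -0.362. This decides nothing about a channel bias of differing strength, because both day 0 arrays correlate at 0.735 and low slopes on their profile then fix the sign. A response of the cells at day 2 should have removed the profile from the B array of that day too, but its slope there was 0.993 against -0.01 on the A array. What weakened the profile on these arrays stays open, and so does how far it may account for the early rise of ribosomal proteins and mitochondrial respiration, with medians of 0.34 and 0.35 once it was removed. The same holds for the fall of both lists between early and late, with medians of -0.89 and -0.20 once it was removed.

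The last pattern was the set of 56 late calls made with the day 0 profile removed, 32 higher and 24 lower, led by Hba-ps3, Ndst2, Mknk2 and Myb. All 56 had the same direction with day 0 subtracted, but both fits use the same late arrays, so this is no independent check. Some were small there, such as Tyms-ps at -0.20 (SE 1.09) and Rps12 at -0.30 (SE 1.04). A bias of the probes that follows the channels should give them the same sign on the SD arrays of days 5 and 6, if these hold the channels in the order of the other arrays. The fit did not use those SD arrays. A first test counted signs and could not decide, with 32 of 53 opposite (60.4 percent, exact interval 46.0 to 73.5, p = 0.169). A second test, chosen after that count, was the correlation across the 53 probes, -0.534 (Spearman -0.444, permutation p = 6.0e-05, and -0.500 without the 2 farthest probes). It decides nothing about a bias, because the order of the channels on these arrays stays open. Large late differences of series A had also been seen already to run the opposite way on them. Individual calls may be false, as 39.2 of 200.8 were in simulated data, whose noise was of equal size on all arrays.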

How the results depend on the processing

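Chosen only after the data were seen were SD arrays turned, the day 0 profile removed, leaving out series A of days 1, 2 and 3, and 2 scalings of the lists.

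Over 1988 values of named genes under the alternatives, 7 changed sign, 79 became past the threshold and the rest kept direction and side. All 7 came from testing ratios against 0, where Tiam1, Ddx3x and Rrs1 late were 0.0205, 0.0320 and 0.64, Rps18 and Cox7c early -0.13 and -0.30, and Rrs1 and Gpr37 early 0.18 and 0.56. Lists reversed there were, early, erythroid transcription factors (-0.91), ribosomal proteins (-0.51), mitochondrial respiration (-0.44) and proteasome (-0.47), and, late, translation (-1.30), mitochondrial respiration (-1.05), proteasome (-0.81) and heat shock (-0.67). That setting leaves the day 0 bias in the ratio by construction. Of 1182 list medians, 104 changed sign, counted as reversed only where a call was involved.

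Counts of 0 became larger as follows, and beyond the construction just named the cause was not tested. The ratio against 0 called 1, 15, 3 and 1 probes on days 3 to 6, 268 late (163 higher, 105 lower) and 30 on any day. The orientation term called 1 on day 2, 1 late and 3 in the trend. Values as deposited called 1 in the trend. With the profile removed there were 3, 7, 20 and 1 on days 3 to 6, 56 late and 22 on any day. With SD arrays also turned there were 7, 15, 9 and 1, then 54 late (30 higher, 24 lower) and 20 on any day. SD arrays turned alone called 0. Without series A of days 1, 2 and 3, day 4 and late each called 1.

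Leaving out each array gave 0 to 1 calls on day 4 and late and 0 in every other contrast. The calls were Hba-ps3 without the day 3 array of series A, or without that of series B, at an unchanged 4.43 log2 late on 6 of 6 arrays. Day 3 is part of neither contrast. Its values for Hba-ps3 were 5.73 in series A and 2.07 in series B, so leaving out either array took that disagreement out of the spread. Where a day kept a single array, it was assumed to vary like the other groups. Hba-ps3 late passed in 8 of 27 alternatives, those without day 3 of series A or B included. It lay at 2.76 to 5.02 log2, with adjusted p in limma from 1.9e-10 to 0.9997 over the alternatives. The lowest came with the profile removed, where the error of the day 0 arrays is left out.

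The series letters were not taken to pair the arrays, because that needed a correlation of deviations over 0.1 in every pair of days, and 14 of 15 had one (0.03 to 0.39). All were above 0, so in deviations from the mean of a day every array of the 6 days with both letters went with its own letter, a hint from the data and not from the design. In the ratios themselves, days 2, 3 and 4 of B correlated better with day 0 of A than with day 0 of B. With the letter as a block, limma called 1 probe on days 4, 5 and 6, late, on any day and in the trend, and 0 elsewhere. It was Hba-ps3 late (adjusted p = 0.00342, 6 of 6 arrays), on day 4 (0.0102) and on day 5 (0.0242), and Ctsl on day 6 (0.0450). Under the block 1 list passed late, nucleolus and ribosome assembly (median -0.67, adjusted p = 0.0360), and 3 passed early.

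Of lists, 2 passed early, 0 late and 2 in late minus early. With an estimated correlation these became 0, 1 and 0, and fry passed 0 early and 0 in late minus early on the genes with 13 values. SD arrays averaged as deposited gave 3 late (DNA replication, mitosis and ribosomal proteins) and 5 in late minus early. The ratio against 0 gave 6 late. Equal spread and quantile normalization each left 1 in late minus early, ribosomal proteins, and lost mitochondrial respiration (adjusted p = 0.0901 and 0.0859). With the profile removed there were 0 early, 4 late and 2 in late minus early (ribosomal proteins lower, ubiquitin enzymes and autophagy higher). Leaving out each array gave 1 to 3 early, 0 to 4 late and 1 to 4 in late minus early. Mitochondrial respiration was lost early without the day 2 array of A (0.94, adjusted p = 0.0937) or day 0 of B (0.64, 0.129), and in late minus early without day 2 or 6 of A or day 4 or 5 of B. Late lists passed without day 6 of A (4, progenitor factors, DNA replication, mitosis, and nucleolus and ribosome assembly), without day 0 of B (4, progenitor factors, DNA replication, mitosis and ribosomal proteins) or without day 5 of B (3, progenitor factors, nucleolus and ribosome assembly, and glycolysis).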

Other observations

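The fits with the profile removed and the count of splits given in this part were chosen only after the results were seen, and the other list tests were planned.

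Mcpt2, a protease of mast cells, lay at -3.14 log2 late on 6 of 6 arrays, although only 10 of the 13 arrays measured it. The preset list of megakaryocyte and mast cell markers that holds it had 3 probes higher and 3 lower, with a median of 0.04. That median was -0.42 with SD arrays turned and averaged in. Leaving out single day 0 or late arrays put it between -0.58 (day 5 of series A) and 0.60 (day 4 of series B). The histone genes H1f2, H3f3b and H2az1 were 2.77, 1.91 and 1.53 log2 higher, on 6 of 6, 6 of 6 and 5 of 5 arrays. Their median was 1.91, and it was -0.29 when ratios were tested against 0. The fatty acid desaturase genes Scd1 and Scd2 were 2.25 and 1.59 log2 higher on 5 of 5 arrays each.

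In the list of ubiquitin enzymes and autophagy, the 4 members with the smallest late p-values were Lamp1, Ctsl, Gabarapl1 and Ctsd. Lamp1 was 2.72 log2 higher on 4 of 4 arrays (1.69 without day 0 of series B), Ctsl 2.34 on 3 of 5, Gabarapl1 1.98 on 5 of 5 and Ctsd 1.27 on 6 of 6. The list had a median of 0.39 with 7 of 8 genes higher (camera in limma, adjusted p = 0.234). Between early and late its median was 0.70 with 6 of 8 higher (adjusted p = 0.193), and with the profile removed it was 0.65 (adjusted p = 0.0166, and 0.0471 with an estimated correlation).

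With the profile removed, 4 lists were lower late by camera in limma. These were ribosomal proteins (median -0.59, adjusted p = 0.000328), DNA replication (-0.56, 0.00755), mitosis (-0.77, 0.00755) and nucleolus and ribosome assembly (-0.68, 0.0447). With an estimated correlation they had adjusted p = 0.176, 0.365, 0.00127 and 0.2996, so that mitosis alone passed under both. For mitosis this was no stricter check. In the main fit its estimated correlation was -0.0971, below the preset 0.01, and a lower correlation makes the test more lenient. The calls of single genes there included Mcm7 at -1.38 and the cytokinesis gene Racgap1 at -1.46.

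For the difference between early and late, the real split of the 9 arrays into 3 and 6 called 0 probes, so that all 84 splits had to give as many and their count decides nothing about chance. The highest of the other splits called 14 and set days 2, 4 and 5 of series B against the rest. The other splits that set series B arrays alone against the rest called 1, 0 and 0. They had 112, 92 and 130 probes at an unadjusted p under 0.05, and splits of series A arrays alone had 32 to 156. These splits therefore do not settle whether the arrays are structured by series, but other values show that the series differed. The standard deviation of the log2 ratios was 0.82 to 1.31 on series A arrays and 1.40 to 1.75 on series B arrays other than SD. Slopes on the day 0 profile on induced days were -0.01 to 0.61 in series A and 0.69 to 1.15 in series B. With the letter as a block the real split called 0 as well. In this fit of the 9 arrays alone, the real split had 72 probes at an unadjusted p under 0.05, the highest other had 197, and 23 splits, the real one included, had at least 72.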
